A study of Homo sapiens with 36 samples.

How the data were processed

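RNA from 2 human cell lines was hybridised to Illumina whole-genome expression bead arrays, 1 sample per array. Per the labels' protocols, cells were grown in flasks, treated samples received cigarette smoke extract (CSE) at 20% for 2 to 6 h, RNA was taken with a phenol reagent, its quality numbers lay between 9.3 and 9.6, and biotin-labelled cRNA was made with a kit for bead arrays. The labels do not give the exposure time of any single sample. They also do not say whether the samples of a group came from separate cultures, so every p-value measures the spread between these samples, which may be technical.

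Each array was placed in its group by the label that names its line and treatment. This gave 12 control and 6 CSE arrays for each line, 36 in all, on 3 BeadChips of 12 arrays. For Jurkat control replicate 7 the title and source name the Jurkat line while the cell line field names DLD-1. It was kept as Jurkat, and all results were recomputed without it. Replicate numbers only name the arrays and pair nothing. Control DLD-1 arrays numbered 3, 4 and 5 on BeadChips 1, 2 and 3, DLD-1 CSE arrays 2, 3 and 1, control Jurkat arrays 4 on each, and Jurkat CSE arrays 3, 1 and 2.

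The main input was the authors' deposited table of average bead intensity per probe for 47323 probes, which is not normalized, per the file headers. All its values are above 0, and the deposited intensity values were therefore treated as not background-subtracted. The table also holds a detection p-value for each probe and array, deposited by the authors, which moves in steps of 1 in 769 and compares a probe with the negative control beads of the same array. The deposited series table holds a further set of intensity values from the authors, on a linear scale. Within each array its ranks follow the bead intensities exactly, and its 36 columns have nearly equal distributions, as quantile normalization gives. The software that made both tables is not given in the sources used here. No per-sample column was left unused.

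Background was corrected with the normal-exponential model of limma's neqc, fitted through the detection p-values, with an offset of 16, followed by quantile normalization and log2 (limma 3.58.1 in R 4.3.3). Probes with a detection p-value under 0.05 on at least 6 arrays were kept, 22612 in all. Of these, 1457 carry only a Unigene cluster name and were left out of the gene tests. Each gene was represented by its brightest kept probe, which mattered for 3974 genes with more than 1 kept probe. Gene names were updated through a table of 59792 genes of assembly GRCh38.p14, used for names only because the files state no genome build. Of the 16028 genes tested, 10902 matched by symbol, 1848 by an older symbol and 1147 by gene number, and 2131 kept the name in the file. Many of the probes detect related transcripts, so copies of a multigene family cannot be separated with certainty.

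A single limma model with a mean for each of the 4 groups was fitted to all 36 arrays, so that the groups share an estimate of the spread. For a gene that varied more with CSE than in controls, this shared estimate can make the SE and p-value too small. Its contrasts were CSE minus control in DLD-1, the same in Jurkat, the difference between these effects (DLD-1 minus Jurkat), and control DLD-1 minus control Jurkat. P-values were adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05. Errors of log2 changes are standard errors (SE) from this model, and errors of group means are standard deviations (SD). A gene not detected on any array of a group has only a bound there, given as a fold of at least the stated size. It sets the brighter group's mean against the mean, over the dim group's arrays, of the higher of the probe's own value and the lowest value among detected probes.

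Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 24 lists with at least 5 measured genes, with camera at a correlation estimated per list and fry beside it. The lists covered heat shock chaperones, NRF2 antioxidant and glutathione genes, aryl hydrocarbon receptor targets, metallothioneins, the unfolded protein response of the endoplasmic reticulum (ER), the ATF4 integrated stress response, anti-apoptotic BCL2 and IAP genes, pro-apoptotic genes, p53 targets, immediate early genes, NF-kB and inflammatory genes, proteasome subunits, autophagy, G2/M and G1/S cell cycle genes, cholesterol synthesis, hypoxia and glycolysis, ribosomal proteins, the mitochondrial respiratory chain, interferon response, genes at inflammatory bowel disease risk loci, and markers of intestinal epithelium, T cells, fibroblasts and monocytes or B cells. A few genes stand in more than 1 list: pro-apoptotic genes and p53 targets share 5 listed genes, and no other pair shares more than 1.

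Named genes followed a rule. It took HSPA6 and BCL2L1 throughout, the 8 largest rises and 8 largest falls past the threshold in each line among genes whose 6 CSE arrays all lay on the same side of the control mean, up to 4 members with the smallest p from each list described, and the 6 largest differences in each direction for the remaining contrasts. Unnamed loci were passed over. The groups, contrasts, lists, this rule and the alternative settings were fixed before the data were examined, apart from 1 alternative noted in the closing section. Chosen after seeing the data were the set of small structural RNAs, the tests that the closing section marks so, and genes named outside the rule for their detection or for a further probe.

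The model was tested on simulated data for DLD-1 with the means and spreads of the 16028 genes, equal spread in all groups and independent genes. It recovered 20 of 50 genes changed by 0.5 on the log2 scale, 48 of 50 changed by 1, and all 50 at 2 and at 3. The simulation also shifted the proteasome list as a whole, and calls among its genes counted as true. Of its 193 calls, 12 (6.22%) were false, and no gene was called in the unchanged Jurkat groups. The real arrays depart from this setting: some genes differed in spread between groups, genes of a list were correlated and arrays deviated in sets. The simulated rate of false calls therefore need not hold for them. The exact rank test used as an alternative gave the same p-values as R's own for 200 simulated genes. The alternatives tried were other background, normalization and offset settings, the authors' normalized values, other filters on dim probes, all probes of a gene, the BeadChip as a block or taken singly, each line fitted alone, array weights, another variance model, a rank test, a size threshold, and leaving out each array in turn or the array with conflicting labels. Levels of sex-linked marker genes are not reported here.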

Results

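The series measured how 2 human cell lines respond to CSE, an aqueous extract of cigarette smoke. DLD-1 is an epithelial line from a colorectal adenocarcinoma, and Jurkat is a line of leukaemic T cells. Each line was measured on 12 control arrays and 6 arrays of CSE-treated cells. Between 16012 and 19131 probes were detected per array (mean 17320), and the median bead intensity per array lay between 97.2 and 121. The number of arrays limits the precision. Adjusted p-values are from limma unless camera is named, and changes are on the log2 scale, from 6 CSE and 12 control arrays per line.

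The series title names HSPA6, an inducible chaperone of the HSP70 family, as a smoke-induced gene, and Bcl-XL, the anti-apoptotic protein encoded by BCL2L1. HSPA6 rose by 6.31 on the log2 scale in DLD-1 (SE 0.51, 79.1-fold, adjusted p = 2.3e-11) and by 5.02 in Jurkat (SE 0.51, 32.5-fold, adjusted p = 2.2e-09). In DLD-1 its normalized log2 intensity was 5.15 ± 0.39 (SD, n = 12) in controls and 11.46 ± 1.76 (SD, n = 6) with CSE. The Jurkat values were 5.19 ± 0.71 (SD, n = 12) and 10.21 ± 1.87 (SD, n = 6). In both lines all 6 CSE arrays lay above all 12 control arrays. HSPA6 varied more with CSE than in controls, so its SE and p-values, which rest on the shared spread, are likely too small. BCL2L1 did not pass the test, with log2 differences of -0.15 (SE 0.16, adjusted p = 0.73) in DLD-1 and -0.28 (SE 0.16, adjusted p = 0.22) in Jurkat. Its control level was 0.87 higher on the log2 scale in DLD-1 than in Jurkat (SE 0.13, adjusted p = 2.0e-07). A further BCL2L1 probe gave changes with CSE of 0.17 in DLD-1 (adjusted p = 0.72) and -0.07 in Jurkat (adjusted p = 0.85).

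The HSPA6 effect did not differ detectably between the lines (difference 1.28, SE 0.72, adjusted p = 0.31; within BeadChips 1, 2 and 3 it was 3.08, 0.72 and -1.91). Another HSPA6 probe gave smaller rises, 4.57 in DLD-1 (adjusted p = 1.0e-08) and 2.66 in Jurkat (adjusted p = 4.5e-05). With the BeadChip as a block the HSPA6 rises were 6.37 and 5.06. Within BeadChips 1, 2 and 3 they were 6.97, 6.77 and 4.08 in DLD-1 and 3.88, 6.05 and 6.00 in Jurkat. The DLD-1 value on BeadChip 3, which holds 1 DLD-1 CSE array, did not pass (adjusted p = 0.23). HSPA6 was detected on 7 of 12 control DLD-1 arrays and 5 of 12 control Jurkat arrays, so its fold rests on a baseline near background. The authors' normalized values, from which no background was taken, gave rises of 4.34 and 3.19. The arrays measure RNA and hold no protein values.

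**Figure D1:**
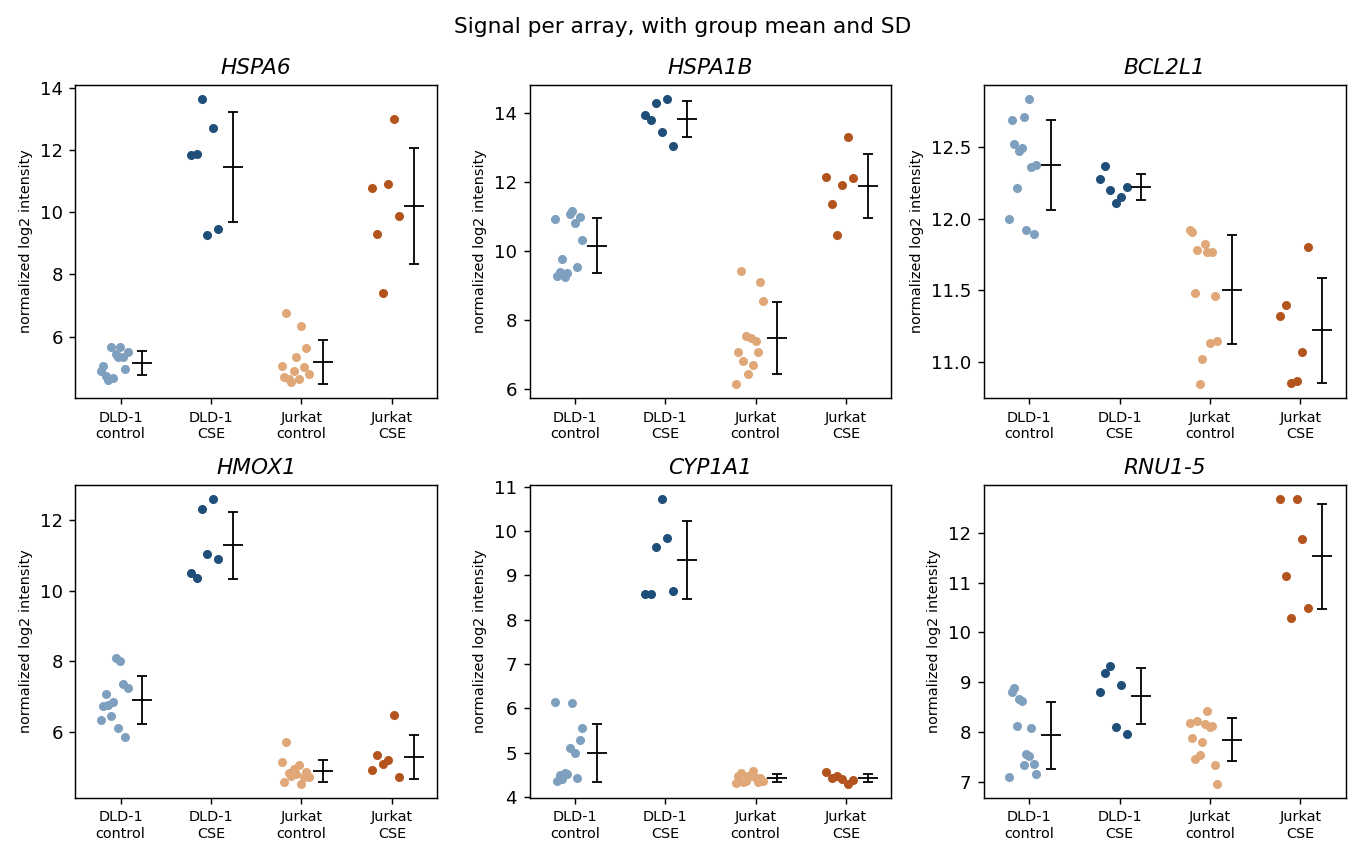
Normalized log2 intensity of 6 genes on each array (points), by cell line and treatment, with the group mean and SD (black bars), 12 control and 6 CSE arrays per line. HSPA6 and HSPA1B rose in both lines, HMOX1 and CYP1A1 passed in DLD-1, RNU1-5 passed in Jurkat, and BCL2L1 passed in neither; axes differ between panels and do not start at 0.

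In DLD-1 cells with CSE, HMOX1, CYP1A1 and 18 of 27 heat shock chaperones rose. HMOX1, which encodes the inducible haem oxygenase, rose by 4.37 (SE 0.29, 20.7-fold, adjusted p = 8.4e-14), and CYP1A1, a cytochrome P450 that oxidises aromatic hydrocarbons, rose by 4.35 (SE 0.25, 20.4-fold, adjusted p = 5.7e-16). CYP1A1 was detected on 5 of 12 control arrays, so its fold rests on a baseline near background, and the authors' normalized values gave 2.43. HSPA1B, which encodes an inducible HSP70, rose by 3.67 (SE 0.40, 12.7-fold, adjusted p = 6.3e-08). TXNIP, the thioredoxin-interacting protein, had the largest named fall, -2.39 (SE 0.23, adjusted p = 4.5e-09), and lay below all 12 controls on all 6 CSE arrays. Altogether 691 of 16028 genes passed, 297 higher and 394 lower with CSE, of which 78 and 24 changed at least 2-fold.

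Further large rises were in HSPA7 (4.22, SE 0.49, adjusted p = 2.1e-07), a pseudogene so close in sequence to HSPA6 that its probe cannot be assigned to that locus with certainty, and TIPARP (2.40, SE 0.25, adjusted p = 1.2e-08), an ADP-ribosyltransferase gene. EID3 (2.39, SE 0.29, adjusted p = 9.6e-07) and the transcription factor gene FOS (2.66, SE 0.73, adjusted p = 0.026) also rose. EID3 was detected on 3 of 12 control arrays and gave 0.98 with the authors' normalized values. FOS lay between 4.59 and 5.45 on 6 control arrays and between 7.35 and 7.72 on the other 6, above 1 CSE array (6.84). Genes that fell included ARID5B (-1.44), ID1 (-1.40), an inhibitor of DNA binding, the kinase gene NUAK2 (-1.33), the death receptor gene TNFRSF25 (-1.30) and the telomerase RNA TERC (-1.29). LFNG, a glycosyltransferase acting on Notch receptors, was at least 1.92-fold lower, being detected on 11 of 12 control and none of the 6 CSE arrays (adjusted p = 4.9e-05), while another LFNG probe gave -0.21 (adjusted p = 0.52). The metallothionein MT1F (-1.32, adjusted p = 0.049) was at the threshold and lost its call in 29 of the 36 fits that left out 1 array, with adjusted p up to 0.14 (without DLD-1 CSE replicate 5). It also lost its call in 14 of 16 other settings. FOS lost its call without DLD-1 CSE replicate 1, 2 or 3 (adjusted p up to 0.082), and ID1 without replicate 3 or 5 (adjusted p up to 0.085).

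The count of genes in DLD-1 rested on few arrays. Leaving out DLD-1 CSE replicate 3 gave 294 genes and leaving out replicate 5 gave 365, while leaving out replicate 6 gave 918. An exact rank test per gene, which is a different test, gave 233. Within BeadChips 1 and 2 the counts were 35 and 628, and with the BeadChip as a block 651. Within BeadChips 1, 2 and 3 HMOX1 gave 3.71, 4.95 and 3.97 (block 4.34), CYP1A1 3.59, 5.43 and 3.37 (block 4.35), HSPA1B 4.02, 4.18 and 2.49 (block 3.83) and TXNIP -1.61, -3.16 and -2.10 (block -2.43). BeadChip 3 holds 1 DLD-1 CSE array, assumed to vary like the other groups, so a count of genes there has little meaning.

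Heat shock chaperones moved as a group in DLD-1. Of 27 measured genes 18 rose and none fell (23 rose and 1 fell adjusted over the list alone), with a median log2 change of 1.10 (camera, adjusted p = 3.3e-34, and adjusted p = 0.0023 with an estimated correlation). Beside HSPA6 and HSPA1B, the smallest p-values were those of the co-chaperone gene DNAJB1 (2.31, SE 0.30, adjusted p = 2.9e-06) and HSPA1A (1.40, SE 0.19, adjusted p = 9.1e-06), whose sequence is so close to that of HSPA1B that their probes cannot be assigned with certainty. The median was 1.15 with the BeadChip as a block and 0.65, 1.70 and 0.38 within BeadChips 1, 2 and 3. Aryl hydrocarbon receptor targets also held with an estimated correlation: 3 of 8 rose, CYP1A1, TIPARP and CYP1B1 (2.84-fold, adjusted p = 3.5e-06), with the same count adjusted over the list alone and a list median of 0.15 (camera, adjusted p = 1.7e-07, and adjusted p = 4.6e-05 with an estimated correlation). Its median was 0.16 with the block and 0.13, 0.32 and 0.20 within BeadChips.

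**Figure D2:**
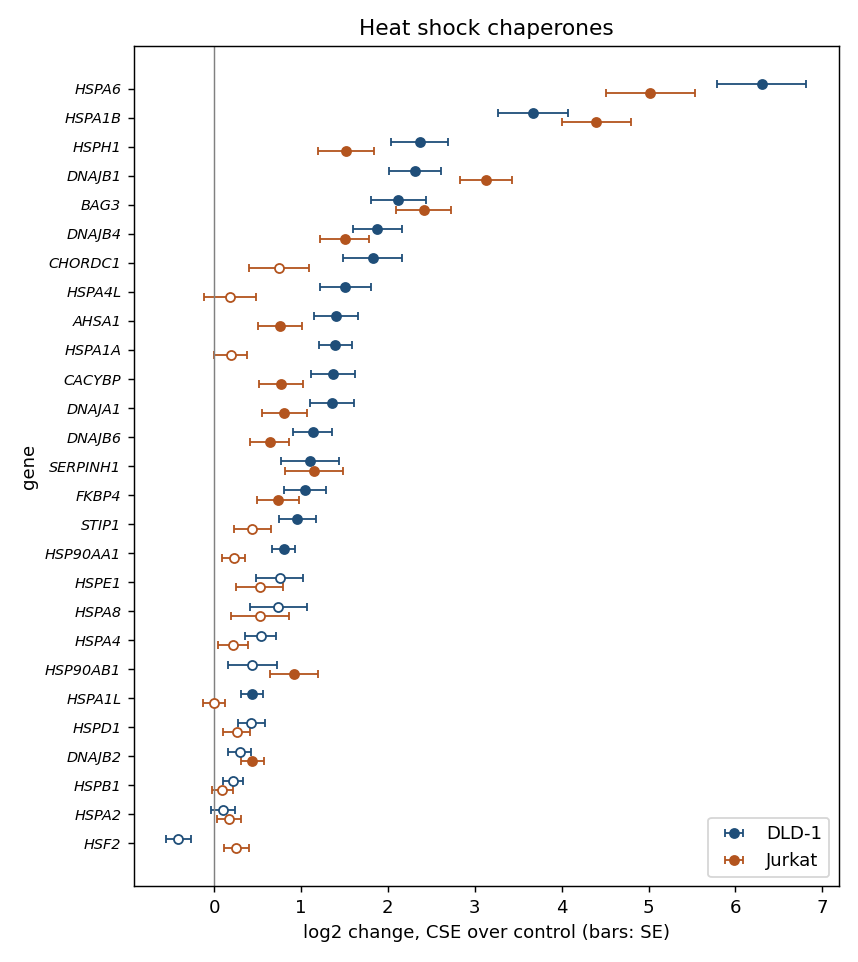
Log2 change with CSE over control for the 27 measured heat shock chaperones in DLD-1 (blue) and Jurkat (orange), ordered by the DLD-1 value; bars are SE and filled points have an adjusted p under 0.05. Filled points number 18 in DLD-1 and 14 in Jurkat, all to the right of 0.

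In DLD-1, 7 of 27 NRF2 antioxidant genes rose and none fell (9 and none adjusted over the list alone). Among them were HMOX1, SRXN1 (1.71, SE 0.25), which encodes sulfiredoxin, GCLM (1.77, SE 0.28), a subunit of the enzyme that starts glutathione synthesis, and MAFG (1.42, SE 0.26). The list's call (camera, adjusted p = 4.4e-11) was lost at adjusted p = 0.0919 with an estimated correlation, while fry called the list (adjusted p = 0.0014). Of 22 genes of the ATF4 integrated stress response 4 rose (5 adjusted over the list alone), namely the cystine transporter SLC7A11 (1.60, SE 0.31; detected on 4 of 12 control arrays), SESN2 (1.18, SE 0.27), ATF3 (2.01, SE 0.52) and PPP1R15A (1.51, SE 0.40). Of 28 immediate early genes 5 rose and 1 fell (10 and 2 adjusted over the list alone). JUN (1.90, SE 0.34), FOSL1 (1.38, SE 0.28) and CCN2 (1.54, SE 0.34) were higher and MYC (-0.71, SE 0.19) lower. Of 21 p53 targets SESN2 and CDKN1A (2.00, SE 0.47), an inhibitor of cyclin-dependent kinases, rose (4 rose and 1 fell adjusted over the list alone). Of 17 hypoxia and glycolysis genes 3 rose (5 adjusted over the list alone), P4HA1 (0.49, SE 0.12), ADM (1.53, SE 0.38) and SLC2A1 (0.64, SE 0.19). These lists were called with camera at adjusted p = 4.8e-05, 4.4e-05, 0.043 and 0.0088 in that order, and each call was lost at adjusted p = 0.315 with an estimated correlation.

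Cell cycle lists had lower medians in DLD-1 with CSE. Of 19 G2/M genes 2 fell (4 adjusted over the list alone), CDC20 (-0.58, SE 0.17) and KIF20A (-0.83, SE 0.25), and of 20 G1/S and DNA replication genes the helicase subunit MCM7 fell (-0.60, SE 0.17; 1 adjusted over the list alone). Further MCM7 probes gave -0.69 and -0.05 without passing. The list medians were -0.38 (camera, adjusted p = 2.3e-06) and -0.44 (adjusted p = 4.4e-05), and both calls were lost at adjusted p = 0.315 with an estimated correlation. For metallothioneins, metal-binding proteins, the median was -1.51, with MT1F lower among 8 genes (4 lower adjusted over the list alone) and values of -1.60 for MT1G, -1.64 for MT1E and -1.52 for MT1A that did not pass over all genes. The camera call (adjusted p = 0.0082) was lost at adjusted p = 0.371 with an estimated correlation. By the brightest probe of each, none of 31 proteasome subunits passed in limma, over all genes or over the list alone, and 2 had an unadjusted p under 0.05. A further PSMD12 probe gave 0.64 and passed (adjusted p = 0.027 over all kept probes). The proteasome median was 0.11 (camera, adjusted p = 0.0082, lost at adjusted p = 0.526 with an estimated correlation).

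With the BeadChip as a block the DLD-1 medians were 0.24 for NRF2 genes, 0.26 for ATF4 genes, 0.31 for immediate early genes, 0.04 for p53 targets, 0.22 for hypoxia genes, -0.36 for G2/M, -0.37 for G1/S, -1.23 for metallothioneins and 0.11 for the proteasome, and the p53 call was lost (adjusted p = 0.11). The p53 call was also lost without DLD-1 control replicate 1, 7, 8 or 9 or DLD-1 CSE replicate 1, 2 or 3, with adjusted p up to 0.14. Within BeadChips 1, 2 and 3 the medians of immediate early genes were 0.26, 0.13 and 0.81, those of NRF2 genes -0.0044, 0.69 and 0.03, and those of ATF4 genes 0.36, 0.07 and 0.40. G2/M gave -0.48, -0.54 and 0.12, G1/S gave -0.26, -0.24 and -0.25, and metallothioneins gave -0.31, -0.54 and -2.35. The medians for p53 targets were 0.13, 0.05 and 0.04, for hypoxia genes 0.13, 0.11 and 0.23, and for the proteasome 0.02, 0.19 and 0.15.

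In Jurkat cells with CSE, HSPA1B, HSPA6 and 22 of 26 small structural RNAs rose and MYC fell. HSPA1B rose by 4.40 (SE 0.40, 21.1-fold, adjusted p = 1.9e-10). RNU1-5, a copy of the U1 spliceosomal RNA, rose by 3.67 (SE 0.31, 12.7-fold, adjusted p = 5.0e-11), and its near-identical copies RNU1-4 and RNU1-3 by 3.57 and 3.56, which are not separate evidence. The 5S ribosomal RNA gene RNA5S9 rose by 3.53 (SE 0.31, adjusted p = 8.3e-11). MYC, which encodes a growth-promoting transcription factor, fell by 1.99 (SE 0.19, 3.98-fold, adjusted p = 3.8e-10). Altogether 3184 of 16028 genes passed, 1330 higher and 1854 lower, of which 94 and 353 changed at least 2-fold. The share of higher genes among those that passed depended on the scaling: it was 41.8% here and 55.3% with median scaling, which placed the median of all genes at 0.15 in place of 0.03.

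GADD45B, a stress-response gene, rose by 3.35 in Jurkat (SE 0.41, 10.2-fold, adjusted p = 9.6e-08), and RASD1, which encodes a small G protein, was at least 7.68-fold higher, detected on 5 of 6 CSE and none of 12 control arrays (adjusted p = 2.4e-07). The remaining named falls were the entry MIR1978 (-2.74, SE 0.35), the small nucleolar RNA SNORA24 (-2.05, SE 0.32), the transcription factor genes ONECUT2 (-1.97, SE 0.17) and KLF2 (-1.86, SE 0.26), TMEM181 (-1.96, SE 0.13), the glucosyltransferase gene ALG10B (-1.86, SE 0.17) and LRRC58 (-1.81, SE 0.20), with adjusted p between 1.7e-13 and 6.3e-06. Each of these falls lay below all 12 controls on all 6 CSE arrays. Further probes of ALG10B (0.0059 and 0.15) and of LRRC58 (-0.34) did not pass. With the BeadChip as a block 3267 genes passed, and within BeadChips 1, 2 and 3 there were 966, 417 and 481, where BeadChip 2 holds 1 Jurkat CSE array. The within-BeadChip values were 3.96, 4.88 and 4.66 for HSPA1B (block 4.41), 3.42, 4.69 and 3.54 for RNU1-5 (block 3.69) and -1.85, -1.90 and -2.46 for MYC (block -2.01).

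Small structural RNAs, a set chosen after its members were seen among the largest rises, numbered 26 and covered spliceosomal, ribosomal, Y and vault RNAs and the RNA parts of RNase P and MRP. The set also holds RN7SK, the pseudogene entry RNU6-15P, and the ribosomal RNAs RNA18SN5 and RNA28SN5, which are not small. Of these, all but RNA18SN5 rose in Jurkat. In Jurkat 22 rose and 1, RNY3, fell (-0.53, adjusted p = 0.010), with a median of 1.47. The RNase P RNA RPPH1 rose by 2.53 (SE 0.27), the RNase MRP RNA RMRP by 2.22 (SE 0.27) and the U11 RNA RNU11 by 2.40 (SE 0.21). In DLD-1 the median was 0.06, and of the 26 the vault RNA VTRNA2-1 (-0.87, adjusted p = 0.0053) and the minor spliceosomal RNA RNU4ATAC (-0.86, adjusted p = 0.029) fell. These RNAs carry no poly(A) tail, where labelling with this kind of kit starts. For replication-dependent histone genes, whose transcripts also lack the tail, the Jurkat median was 0.26, with 7 of 29 higher.

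Among the lists in Jurkat, 14 of 27 heat shock chaperones rose and none fell (14 and none adjusted over the list alone), with HSPA1B, DNAJB1 (3.13, SE 0.30), HSPA6 and BAG3 (2.41, SE 0.32) first. Their median was 0.64 (camera, adjusted p = 3.0e-09, lost at adjusted p = 0.448 with an estimated correlation). Of 22 ATF4 genes 8 rose (12 adjusted over the list alone), including the amino acid transporter subunit SLC3A2 (0.73, SE 0.15), PPP1R15A (1.98, SE 0.40), ATF3 (2.18, SE 0.52) and ATF4 itself (0.64, SE 0.16). The ATF4 median was 0.65 (camera, adjusted p = 0.00017, lost at adjusted p = 0.521 with an estimated correlation). Of 28 immediate early genes 10 rose and 2 fell (12 and 2 adjusted over the list alone). JUN (2.37, SE 0.34) and FOSB (2.65, SE 0.46) were higher and MYC and KLF2 lower (camera, adjusted p = 0.028, lost at adjusted p = 0.839 with an estimated correlation). Of 9 anti-apoptotic genes 4 fell and none rose (4 and none adjusted over the list alone), XIAP (-1.22, SE 0.17), BCL2 (-1.10, SE 0.18), BIRC3 (adjusted p = 0.00026) and BCL2L2, which was near background with detection on 2 of 12 control and none of 6 CSE arrays. Their median was -0.28 (camera, adjusted p = 0.019, lost at adjusted p = 0.448 with an estimated correlation). Of the remaining BCL2 probes, 1 fell by 1.28 (adjusted p = 2.9e-08) and 1 rose by 0.45 (adjusted p = 0.018).

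With the BeadChip as a block these Jurkat medians were 0.69 for heat shock, 0.67 for ATF4, 0.53 for immediate early and -0.29 for anti-apoptotic genes. Within BeadChips 1, 2 and 3 they were 0.43, 1.01 and 0.65 for heat shock, 0.57, 0.40 and 0.81 for ATF4, 0.33, -0.0034 and 1.32 for immediate early genes, and -0.30, -0.50 and -0.22 for anti-apoptotic genes. As many as 4 called lists also arose in most random regroupings of the Jurkat arrays, so that count does not exceed chance. Fry called 5. It asks whether a list moves on balance, without the comparison with other genes that camera makes. Since 3184 of 16028 genes passed in Jurkat, a fry call does not by itself set a list apart from other genes. Fry's adjusted p-values were 0.00018 for heat shock, 0.0056 for ATF4, 0.00011 for anti-apoptotic, 0.035 for pro-apoptotic and 0.00018 for ribosomal protein genes. The regroupings were not repeated with fry. The immediate early call was lost with median scaling (adjusted p = 0.084) and without Jurkat CSE replicate 2 or 5 or Jurkat control replicate 3, 11 or 12 (adjusted p up to 0.066).

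**Figure D3:**
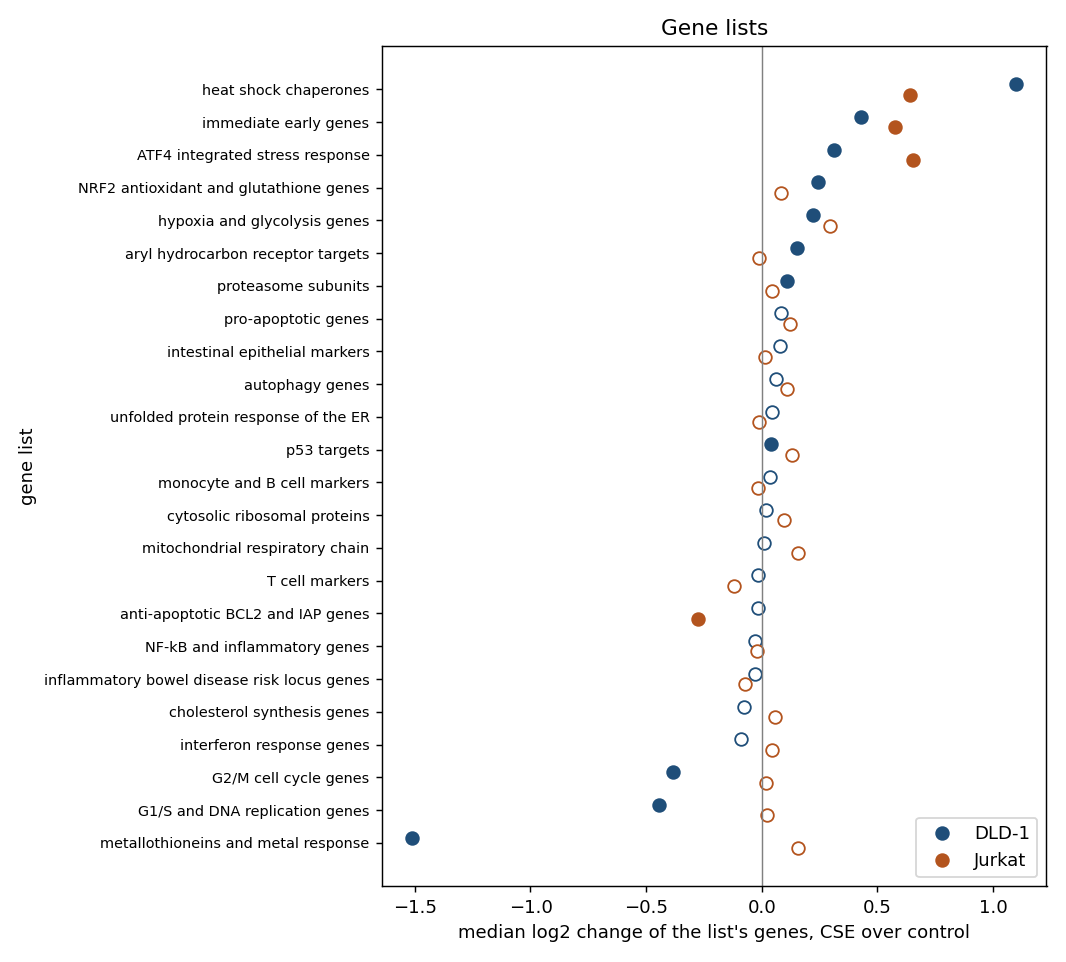
Median log2 change with CSE over control of each gene list's measured genes in DLD-1 (blue) and Jurkat (orange), ordered by the DLD-1 value; filled points have a camera adjusted p under 0.05 at the preset correlation. Heat shock chaperones have the highest DLD-1 median (1.10) and metallothioneins the lowest (-1.51), and 11 points are filled in DLD-1 against 4 in Jurkat.

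The remaining lists were not called with camera at the main settings in the line for which they are given here. In DLD-1 the ER chaperone genes DNAJB9 (1.21) and DNAJC3 (0.82) rose and SYVN1 (-0.57) fell among 19 genes of the unfolded protein response. In Jurkat DNAJB9 (0.93) rose while CANX (-0.66) and SYVN1 (-0.56) fell, with the same counts adjusted over the list alone. MCL1, an anti-apoptotic gene, rose in DLD-1 (0.91, SE 0.18, adjusted p = 0.0015) as 1 of 9, also over the list alone. The anti-apoptotic median was -0.02, its mean 0.05 and its camera direction up. Of 21 pro-apoptotic genes DIABLO (0.51), HRK (0.55) and CASP9 (0.52) rose and APAF1 (-0.82) and TNFRSF1A (-0.57) fell in Jurkat (5 and 2 adjusted over the list alone), while another APAF1 probe gave 0.27 (adjusted p = 0.31). In DLD-1 none passed over all genes by its brightest probe (limma), 2 rose and 1 fell adjusted over the list alone, and 5 had an unadjusted p under 0.05. A further PMAIP1 probe gave 0.88 there and passed (adjusted p = 0.048 over all kept probes). In Jurkat 4 p53 targets rose, PPM1D (0.86), CDKN1A (1.93), GADD45A (1.05) and SESN2 (0.89), and BTG2 (-0.58) fell (6 and 1 adjusted over the list alone). Of 13 NF-kB genes IL18 (-0.99) and BIRC3 fell in Jurkat, as over the list alone, and none passed in DLD-1 by its brightest probe (1 rose and 2 fell adjusted over the list alone, 5 at an unadjusted p under 0.05). A further CXCL8 probe gave 1.27 in DLD-1 and passed (adjusted p = 0.010 over all kept probes).

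Of 14 autophagy genes MAP1LC3B (1.09) rose and ULK1 (-0.63) fell in DLD-1 (2 and 1 adjusted over the list alone), and GABARAPL1 (0.58) rose and ULK1 (-0.96) fell in Jurkat, as over the list alone. In Jurkat 5 of 19 G2/M genes fell, CENPF (-0.78), CENPE (-0.70), TTK (-0.69), KIF11 (-0.59) and TOP2A (-0.51), as over the list alone, although the list median was 0.02 against a mean of -0.18 and a camera direction of down. None of the G1/S genes passed in Jurkat in limma by its brightest probe, and 1 had an unadjusted p under 0.05. A further RRM2 probe gave -1.22 and passed (adjusted p = 3.1e-06 over all kept probes). Their median was 0.02 and the camera direction was down. Of 29 genes at inflammatory bowel disease risk loci, a list that holds HSPA6 because of the series title and is not independent evidence for it, HSPA6 and the prostaglandin receptor gene PTGER4 (0.95) rose and TYK2 (-0.52) fell in DLD-1. In Jurkat HSPA6, SLC22A4 (0.40) and TYK2 (0.41) rose and 5 fell, among them IL10 (-0.99), CCR6 (-0.48) and PTGER4 (-0.70), and the counts were the same adjusted over the list alone. Medians and means of this list opposed each other, at -0.03 and 0.20 in DLD-1 (camera direction up) and -0.07 and 0.03 in Jurkat (down).

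In Jurkat, of 27 NRF2 genes FTL (0.34) rose and GCLC (-0.57) fell (1 and none adjusted over the list alone). In the same line, of 8 aryl hydrocarbon receptor targets TIPARP (1.36) rose, also over the list alone, with a list median of -0.01, a mean of 0.14 and a camera direction of up. Of the metallothionein list the zinc transporter gene SLC39A10 (-0.64) fell, also over the list alone. SREBF1 (-0.77) fell in DLD-1, also over the list alone, and INSIG1 (-0.80) in Jurkat, though not over the list alone, among 20 cholesterol synthesis genes. In Jurkat ADM (1.75) rose among 17 hypoxia genes, also over the list alone. PSMD4 (0.39) rose and PSMD12 (-0.67) fell among proteasome subunits, as over the list alone, while further PSMD12 probes gave -0.11 and 0.08 without passing. ISG15 (0.42) and IRF7 (0.65) rose among 15 interferon genes, as over the list alone. RPS9 (0.35) and RPS14 (0.23) rose among 30 ribosomal protein genes (1 adjusted over the list alone) and COX5B (0.22) and NDUFA1 (0.26) among 27 respiratory chain genes (none adjusted over the list alone). No gene of the ribosomal, respiratory chain and interferon lists passed in DLD-1 in limma, with 1, 2 and 2 genes at an unadjusted p under 0.05. The respiratory chain's DLD-1 median was 0.01, its mean -0.01 and its camera direction down. In Jurkat its camera test was at the threshold (median 0.16, adjusted p = 0.052), and 10 of 17 alternative settings called it, with adjusted p down to 0.0027, though not with an estimated correlation (adjusted p = 0.84). In the line where each passed, another probe of ID1, SREBF1, ATF4, CENPE, KIF11, GADD45A, GCLC, INSIG1, IRF7, SLC22A4, PTPRC and DUSP10 had the same sign without passing. For ATF4 (1.09, limma adjusted p = 0.00068) and DUSP10 (0.50, adjusted p = 0.020) yet another probe did pass in Jurkat over all kept probes. Further probes also passed over all kept probes where the brightest did not. In DLD-1 these were of ATG16L1 (0.77), GADD45A (1.13), HSPA4 (0.85), SLC3A2 (0.78 and 0.79) and LRRC58 (0.57). In Jurkat they included those of CD79B (0.43), GCLM (-0.80), PMAIP1 (0.76), PSMD13 (0.69), RPL10A (0.33), SOD2 (0.67) and ZMAT3 (-1.13).

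Of 19 epithelial markers none passed with CSE in either line in limma, over all genes or over the list alone, with 2 at an unadjusted p under 0.05 in DLD-1 and 0 in Jurkat. Of 20 T cell markers BCL11B (-1.65, SE 0.17), RAG1 (-1.07, SE 0.14), GATA3 (-0.95, SE 0.21) and PTPRC (-0.54) fell in Jurkat, and CD5 (0.60, SE 0.13) and CD7 (0.28) rose, as over the list alone. In Jurkat CD14 (0.58) rose and CD68 (-0.60) and FCGR3A (-0.60) fell among 6 monocyte and B cell markers (2 and 2 adjusted over the list alone), while further CD68 probes gave -0.06 and -0.03 without passing. Of 2 measured fibroblast markers, too few to test as a list, THY1 (0.43) rose. None of these non-epithelial markers passed in DLD-1 in limma, with 0 at an unadjusted p under 0.05.

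HMOX1, CYP1A1, ID2 and GADD45B were among the genes whose response differed between the lines. HMOX1 rose by 3.97 more on the log2 scale in DLD-1 than in Jurkat (SE 0.41, adjusted p = 4.5e-08), where it was detected on 3 of 12 control and 3 of 6 CSE arrays. CYP1A1, which rose 20.4-fold in DLD-1, passed the test of the difference (adjusted p = 5.6e-11), but was not detected on any Jurkat array, so the size of its difference was not measured. ID2, an inhibitor of DNA binding, rose by 3.10 in Jurkat and had a value of -1.31 in DLD-1 that did not pass, a difference of -4.40 (SE 0.69, adjusted p = 0.00011). GADD45B differed by -3.16 (SE 0.58, adjusted p = 0.00066). Altogether the CSE effect differed for 1041 genes, 662 with the higher effect in DLD-1 and 379 with the higher in Jurkat, a share of 63.6% that became 51.0% with median scaling, where the median of all genes was -0.13.

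Also among the largest differences were OSGIN1 (2.14, SE 0.61), which rose in DLD-1, MIR1978 (2.15, SE 0.50) and KLF2 (2.13, SE 0.37), which fell in Jurkat, and the U3 small nucleolar RNAs SNORD3A (-2.97, SE 0.48) and SNORD3D (-2.84, SE 0.42), RNU1-5 (-2.88, SE 0.44) and RNA5S9 (-2.85, SE 0.43), which rose in Jurkat. FAM43A rose in DLD-1 and passed the test of the difference (adjusted p = 4.5e-08), again without detection on any Jurkat array. The difference for OSGIN1 (adjusted p = 0.029) lost its call without Jurkat CSE replicate 1 or 2 or DLD-1 CSE replicate 3, 4 or 5 (adjusted p up to 0.072). Of the 1041 genes 774 had passed in Jurkat and not DLD-1, 140 in DLD-1 and not Jurkat, 21 in both in the same direction, 13 in both in opposite directions and 93 in neither. Without Jurkat CSE replicate 1 the count was 620, and without DLD-1 CSE replicate 3 or 5 it was 630 or 639. With the BeadChip as a block it was 985, and within BeadChips 1, 2 and 3 it was 5, 169 and 0 in limma, the last with 1210 genes at an unadjusted p under 0.05. BeadChip 2 holds 1 Jurkat CSE array and BeadChip 3 holds 1 DLD-1 CSE array. The within-BeadChip differences were 3.66, 4.63 and 3.08 for HMOX1 (block 3.87), -3.36, -5.84 and -3.95 for ID2 (block -4.53) and -2.77, -3.99 and -3.72 for GADD45B (block -3.32).

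By list, aryl hydrocarbon receptor targets had the higher fitted response in DLD-1: CYP1A1 and CYP1B1 (1.54, SE 0.28) passed among 8 (3 adjusted over the list alone), and the median difference was 0.35 (camera, adjusted p = 0.0018, and adjusted p = 0.0105 with an estimated correlation). CYP1A1 and UGT1A6, the latter named after its values were seen, were not detected on any Jurkat array, so this median rests in part on values at background. Of 27 NRF2 genes 7 had the higher response in DLD-1 and none the lower (8 and none adjusted over the list alone). They included GCLM (1.99, SE 0.40), SRXN1 (1.79, SE 0.36) and MAFG (1.78, SE 0.37), and the list median was 0.15 (camera, adjusted p = 0.0014, lost at adjusted p = 0.80 with an estimated correlation). The anti-apoptotic genes XIAP (1.40, SE 0.24) and BCL2 (1.14, SE 0.26) differed among 9 (3 adjusted over the list alone), with a median of 0.29 (camera, adjusted p = 0.0058, lost at adjusted p = 0.151 with an estimated correlation). Fry called this list (adjusted p = 0.0016). In DLD-1 BCL2 was detected on 1 of 12 control and none of 6 CSE arrays, so its difference rests on values at background there. None of 20 G1/S genes passed in limma, over all genes or over the list alone, and 5 had an unadjusted p under 0.05. The G1/S median was -0.35 (camera, adjusted p = 0.033, lost at adjusted p = 0.86 with an estimated correlation, and without DLD-1 control replicate 1, 8, 11 or 12, DLD-1 CSE replicate 1, 2, 3 or 5, or Jurkat CSE replicate 3 or 6, with adjusted p up to 0.18), and 8 of 16 alternative settings lost the call. With the block these medians were 0.33, 0.14, 0.30 and -0.32. Within BeadChips 1, 2 and 3 they were 0.08, 0.40 and 0.31 for aryl hydrocarbon receptor targets, -0.18, 0.48 and 0.22 for NRF2, 0.48, 0.60 and 0.18 for anti-apoptotic and -0.26, -0.15 and -0.23 for G1/S genes. Among random regroupings of the arrays, 4 called lists were common, so this count does not exceed chance, and without DLD-1 CSE replicate 6 it was 7.

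Of the lists whose response was not called as different at the main settings, heat shock chaperones had a higher response in DLD-1 for HSPA1A (1.20, SE 0.27) and HSPA4L (1.33, SE 0.42) and a lower one for HSF2 (-0.66, SE 0.20), 3 and 1 adjusted over the list alone. The list's camera test was at the threshold (adjusted p = 0.055), and 9 of 16 alternative settings called it, with adjusted p down to 0.0086, though not with an estimated correlation (adjusted p = 0.86). In Jurkat HSPA1A was detected on 1 of 6 CSE arrays and no control array, so its difference rests on values at background there. PTGER4 (1.65, SE 0.23), which had risen in DLD-1 and fallen in Jurkat, and TYK2 (-0.93, SE 0.21), which had done the reverse, differed among the bowel disease genes. BCL11B, RAG1 and CD5 passed the test of the difference among T cell markers, but BCL11B and CD5 were detected on none of the DLD-1 arrays and RAG1 on 1. MYC (1.28, SE 0.26), KLF2 and DUSP10 (-1.44, SE 0.34) differed among immediate early genes.

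The lines also shared part of the response. Of the genes that passed, 79 were higher in both lines against 24.6 for independent lists, and 161 were lower in both against 45.6. Opposite calls were fewer than independent lists would give, 5 genes higher in DLD-1 and lower in Jurkat against 34.4, and 8 the other way against 32.7. Across all 16028 genes the log2 changes of the lines had Pearson's r = 0.348 and Spearman's rho = 0.253, computed across genes, which are not independent replicates. The lines have separate control arrays.

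**Figure D4:**
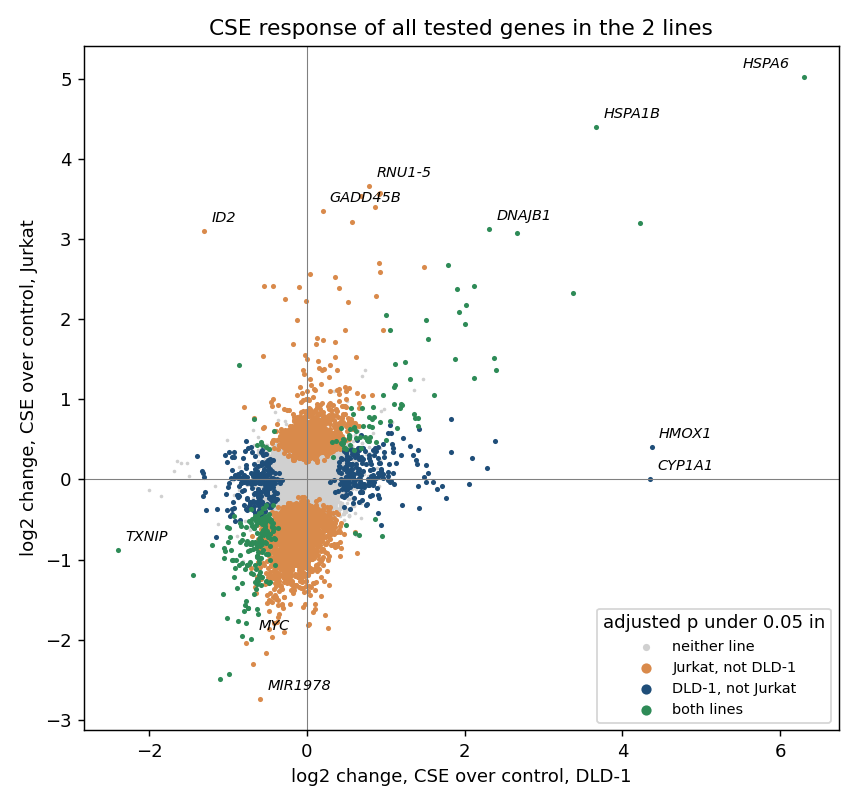
Log2 change with CSE over control in DLD-1 (x) against Jurkat (y) for all 16028 genes, coloured by the line in which the adjusted p was under 0.05. HSPA6 and HSPA1B lie far up on both axes, HMOX1 and CYP1A1, the latter undetected in Jurkat, far along the DLD-1 axis, and RNU1-5, GADD45B and ID2 far along the Jurkat axis.

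Untreated DLD-1 and Jurkat cells differed in their lineage genes. In DLD-1 the calcium-binding protein gene S100P was higher by 8.23 on the log2 scale (SE 0.26) and the epithelial adhesion gene EPCAM was 256-fold higher, both on all 12 arrays. The keratin gene KRT19 was higher by 7.85 (SE 0.19), AGR2 by 7.63 (SE 0.19), the forkhead gene FOXQ1 by 7.59 (SE 0.19) and FLJ40504 by 7.57 (SE 0.22). In Jurkat the T cell receptor subunit gene CD3D was higher (fitted -8.63, SE 0.14), as were ALDH1A2 (-7.67, SE 0.14), ITM2A (-7.65, SE 0.14), TSPAN7 (-7.55, SE 0.15) and the leukocyte gene LCP1 (-7.48, SE 0.14). DNTT, which encodes terminal deoxynucleotidyl transferase, was at least 154-fold higher in Jurkat. Each of these separated all 12 arrays of 1 line from all 12 of the other. The other sizes rest on baselines near background. On Jurkat arrays KRT19 was detected on 2 of 12, AGR2 on 3, FOXQ1 on 4, S100P on 5, EPCAM on 6 and FLJ40504 on 8. On DLD-1 arrays CD3D was detected on 1 of 12, TSPAN7 on 5, ITM2A on 7, LCP1 on 9 and ALDH1A2 on 11. Of 16028 genes 10087 differed, 4725 higher in DLD-1 and 5362 in Jurkat, a share of 46.8% that became 56.8% with median scaling, where the median of all genes was 0.13.

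Of 19 epithelial markers 17 were higher in DLD-1 (17 adjusted over the list alone; median 3.83, camera, adjusted p = 2.6e-13, and adjusted p = 0.00041 with an estimated correlation). All 20 T cell markers were higher in Jurkat (20 adjusted over the list alone; median -4.71, camera, adjusted p = 2.9e-18, and adjusted p = 0.0015 with an estimated correlation). Aryl hydrocarbon receptor targets were already higher in control DLD-1 for 7 of 8 genes and lower for 1, as over the list alone (median 2.43, adjusted p = 0.0024 with an estimated correlation). For NRF2 genes 22 of 27 were higher and none lower (23 and none adjusted over the list alone), a call lost at adjusted p = 0.203 with an estimated correlation. All 8 metallothionein list genes were higher in DLD-1 (8 adjusted over the list alone), lost at adjusted p = 0.769 with an estimated correlation. For G1/S, 16 of 20 genes were lower (16 adjusted over the list alone), lost at adjusted p = 0.677 with an estimated correlation. The summed signal of epithelial markers on Jurkat control replicates 5 and 7 was 1.65% and 1.16% of its control DLD-1 mean, against 0.418% to 0.655% on the other 10 Jurkat control arrays and 0.501% to 0.920% on the Jurkat CSE arrays.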

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

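Tests of the epithelial signal on 2 Jurkat control arrays and of the sets of similar arrays, and the alternative without those 2 arrays, were chosen after the result was seen. The differences below are DLD-1 minus Jurkat and stood out because the CSE effect itself differed between the lines by limma's test (adjusted p under 0.05). SE and adjusted p, printed as p, are given for only some of them.

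HMOX1 differed by 3.97 (SE 0.41, p = 4.5e-08), EID3 by 1.91 and OSGIN1 by 2.14 (SE 0.61, p = 0.029), each having risen in DLD-1. CYP1A1 (fitted 4.35, p = 5.6e-11) and FAM43A (fitted 2.11, p = 4.5e-08) also rose there, and NUAK2 (fitted -1.43) fell, but all 3 were undetected on every Jurkat array. LFNG (fitted -1.10) was undetected on all 6 DLD-1 CSE arrays, RASD1 (fitted -2.54) on all 12 Jurkat control arrays and ONECUT2 (fitted 1.52) on all 6 DLD-1 CSE arrays. The fitted values of these 6 genes are not measured sizes. The falls in DLD-1 exceeded the Jurkat change for TXNIP (-1.51), which fell in both lines, ID1 (-1.69) and TNFRSF25 (-1.33). RNU1-5 (-2.88), RNU1-4 (-2.64), RNU1-3 (-2.64), RNA5S9 (-2.85), SNORD3A (-2.97), SNORD3D (-2.84), GADD45B (-3.16) and ID2 (-4.40) had the higher response in Jurkat. The fall in Jurkat exceeded the DLD-1 change for MIR1978 (2.15), KLF2 (2.13), LRRC58 (1.83), ALG10B (1.38), MYC (1.28) and TMEM181 (1.13). Among lists, the median difference was 0.15 for NRF2 genes, 0.35 for aryl hydrocarbon receptor targets, 0.29 for anti-apoptotic genes and -0.35 for G1/S genes, of which the receptor targets alone held with an estimated correlation. Outside the gene tests, 4 of 1457 probes named by a Unigene cluster alone were higher with CSE in DLD-1 and 22 lower, and in Jurkat 27 were higher and 128 lower.

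Chance regrouping of the arrays was tried with 100 splits per comparison, the real one included. For the gene counts, 1 split of 100, the real one, reached each. They were 691 in DLD-1 (highest other 34), 3184 in Jurkat (1359), 1041 for the difference (281) and 10087 between the lines (4478). Chance is therefore unlikely for these counts. It is not excluded, because the splits treat arrays as independent and exchangeable, which the sets of similar arrays described below call into question. For the 11 lists in DLD-1, 2 splits reached the count, the real one and 1 other, which is under the set limit of 5 of 100. The other splits had a median of 5 called lists, and 95 of them called at least 1. Chance is therefore unlikely for the count of 11 but not excluded, and single called lists may arise by chance. Nor can chance be excluded for the 4 lists in Jurkat, reached by 63 splits (highest other 10). The same holds for the 4 lists that differ, also reached by 63 (highest other 9).

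Small structural RNAs rose on the Jurkat CSE arrays, 22 of 26 with a median of 1.47, and 21 of the 26 had a higher response there than in DLD-1 by the test of the difference. Quantile normalization as the cause is argued against by a median of 1.46 with median scaling. An equal rise in labelling of all RNA without a poly(A) tail is argued against by a median of 0.26 for replication-dependent histone genes (interquartile range 0.38). That argument assumes that CSE did not itself lower the transcripts of these histone genes, which was not tested. Those genes did move up in Jurkat, 7 of 29 higher and 0 lower, while the median of protein-coding genes was 0.02. A smaller rise in labelling of all such RNA is therefore not excluded. The 6 arrays deviated by 2.04, 1.11, 0.80, 2.34, 1.67 and 0.77 from the control mean. A response of Jurkat cells to CSE and a change in labelling of this RNA class alone stay open, since neither was tested.

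Jurkat control replicates 5 and 7 carried epithelial marker signal of 1.65% and 1.16% of control DLD-1. That the latter array, whose labels conflict, is a DLD-1 sample is excluded by the 1.16%. DLD-1 RNA in these samples and another source cannot be told apart: of the 100 genes highest in DLD-1, 92% and 88% were brighter there than on the other Jurkat controls, against 30% to 78% on the remaining arrays, and the lower value falls between the limits set for and against. No biological explanation was tested. Without both arrays 680, 3098, 969 and 9880 genes passed in the order of the contrasts, against 691, 3184, 1041 and 10087.

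Arrays of a group deviated from their group mean in sets, with correlations of deviations up to 0.56 among DLD-1 controls and 0.55 among Jurkat controls. FOS split the DLD-1 controls into a lower and a higher set and the Jurkat controls into a lower, a middle and a higher set. On DLD-1 controls it was 4.59 to 5.45 on replicates 1, 7, 8, 9, 11 and 12 and 7.35 to 7.72 on the others. On Jurkat controls it was 4.42 to 5.05 on replicates 3, 5, 11 and 12, 6.58 and 6.79 on replicates 2 and 7, and 8.27 to 9.59 on the others. The array most similar to each control lay in the same set. The contrasts and regroupings treated all controls of a line as exchangeable, which these sets call into question. The BeadChip cannot be told apart from other sources: 11 of 36 arrays had their most similar array on the same BeadChip, against 9.93 for random assignment (permutation p = 0.42). Signal level cannot be told apart either, with a median difference of 592 detected probes against 651 (permutation p = 0.37). Exposure time or separate cultures may also lie behind these sets, and the labels give neither per sample.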

How the results depend on the processing

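The alternative without the 2 Jurkat control arrays with epithelial signal was chosen after seeing the data. Across settings other than single BeadChips, left-out single arrays, the rank test and the size threshold, 553 to 838 genes passed in DLD-1 and 2839 to 4096 in Jurkat, and HSPA6 rose by 4.34 to 6.37 and 3.19 to 5.21. The cause of the changes below was not tested, except that single BeadChips and left-out arrays hold fewer arrays. With an estimated correlation 2, 0 and 1 lists were called in DLD-1, Jurkat and the difference, against 11, 4 and 4; fry called 3, 5 and 2. At 2-fold or more, 102, 447, 303 and 3987 genes passed in the order of the contrasts. The exact rank test called 233 genes in DLD-1. With no filter on dim probes 7 lists differed between the lines, and with median scaling the respiratory chain's camera direction in DLD-1 turned up (median 0.14).

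Within BeadChip 1, 35 genes passed in DLD-1, 966 in Jurkat and 5 for the difference, with 5 lists in DLD-1 and 2 for the difference, and the NRF2 difference was -0.18. Within BeadChip 2, 417 genes passed in Jurkat and 169 for the difference, with 6 lists in DLD-1 and 7 in Jurkat. BeadChip 2 holds 1 Jurkat CSE array and BeadChip 3 holds 1 DLD-1 CSE array, assumed to vary like the other groups. Within BeadChip 3, 1 gene passed in DLD-1, 481 in Jurkat and 0 in limma for the difference (1210 at an unadjusted p under 0.05), and HSPA6 rose by 4.08 in DLD-1 without passing. There the DLD-1 camera direction of the respiratory chain turned up (median 0.25), and the medians reversed to 0.12 for G2/M in DLD-1, to -0.36 for cholesterol synthesis in Jurkat, and to 0.66, 0.41 and 0.21 for the differences of G2/M, cholesterol synthesis and the respiratory chain.

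Leaving out 1 array gave 294 to 918 genes in DLD-1, 2436 to 3200 in Jurkat, 620 to 1237 for the difference and 3 to 7 lists for the difference, and HSPA6 rises of 5.87 to 6.75 and 4.46 to 5.58. Of 2232 named gene results in these fits 2193 kept their side of the threshold and, where called, their direction, and 39 lost their call. Of 2592 list results 2535 did, 22 lost and 35 gained a call. Direction was not compared for results that were called in neither fit. Each line fitted alone gives no difference. No paired analysis was possible because the labels give no replicate numbers shared between groups. Signal over background limits the fold of genes dim in controls, such as HSPA6.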

Other observations

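The counts of small nucleolar RNAs were chosen after small structural RNAs were seen to rise. Among the 3622 genes that passed in either line, 70.0% had log2 changes of the same sign in both, with Pearson's r = 0.456 across genes, which are not independent replicates. DNAJB1 (2.31 in DLD-1 and 3.13 in Jurkat), CDKN1A (2.00 and 1.93), ATF3 (2.01 and 2.18) and JUN (1.90 and 2.37) are named genes that rose in both lines, and TXNIP (-2.39 and -0.88) and ULK1 (-0.63 and -0.96) fell in both. Of 142 small nucleolar and Cajal body RNAs, many of which guide the modification of other RNAs, 36 rose and 18 fell in Jurkat, with a median of 0.08, and in DLD-1 2 rose and 3 fell, with a median of 0.02.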
